A study of Mus musculus with 24 samples.

How the data were processed

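Bulk RNA sequencing of mouse kidney was analysed in 24 libraries from 2 separate experiments. In the knockout experiment, per the series design and the sample titles, mice with a tamoxifen-inducible, Cre-mediated deletion of Enpp1 (n = 6) and Cre-negative wild-type mice (n = 6) received an adenine diet for 14 days, and a chow-fed group (n = 4) served as the control. In the antibody experiment, mice on the adenine diet for 14 days received a monoclonal antibody to human ENPP1 (n = 4) or control IgG (n = 4) by intraperitoneal injection at 50 mg/kg. Stranded libraries were made from 400 ng of total RNA, per the labels' protocols. Each library was read as a separate mouse, as far as the labels say; where 2 libraries shared an animal, p-values would measure only the spread between these samples. Sex, age and strain of the mice, the genotype of the chow group, and whether the mice of the antibody experiment carried human ENPP1 are not given in the sources used here. Comparisons with chow may therefore include a difference of genotype.

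Transcripts were quantified with Salmon against GRCm39, per the submitters' processing notes, which also name FastQC, DESeq and DESeq2; their versions and options are not given in the sources used here. The authors deposited estimated read counts per transcript, which are expected counts that need not be whole and are not normalized, per the file headers. The deposited TPM values were scaled by the authors' Salmon run; they were read to check the files and entered no test. Effective transcript lengths, per the file headers, were used only as an offset in an alternative setting. Replicates had not been pooled.

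Transcripts were assigned to genes through their identifiers, without version numbers, in the GENCODE M21 annotation of the mouse assembly GRCm38, the only annotation at hand. Of 116755 transcript identifiers, 115636 matched (99.0%) and 1119 did not; the unmatched transcripts held 0.45% to 0.57% of the reads of a library and were left out of library sizes and tests. Because the annotation and the submitters' assembly differ, no coordinates are given. Estimated counts were summed per gene, giving 35413 genes, and rounded to whole numbers. Reads shared between near-identical genes were divided by the authors' quantification, so values of multicopy genes (the globins, Sprr2f, Ces1g, Cyp2d12, Ugt1a5, Vmn2r113, Rpl9-ps6 and Gm49388) are uncertain.

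Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after filterByExpr on the groups and TMM scaling, with Benjamini-Hochberg adjusted p-values called at a threshold of 0.05. The 16 libraries of the knockout experiment shared a fit without covariates, which gave wild-type adenine against chow, knockout against wild type on adenine, and knockout adenine against chow. The 8 libraries of the antibody experiment had a fit of their own. A fit of the 20 adenine libraries tested the knockout effect minus the antibody effect. CPM values are scaled by TMM, and are given as mean ± SD over the libraries of a group. Log2 changes carry the standard error derived from the F statistic. The 95% intervals use its total degrees of freedom, which are the residual ones plus those that edgeR adds by sharing the spread over genes. All tests are two-sided. For genes with at most 3 reads over the 4 libraries of a group, the fitted change depends on the prior count and is not given; a ratio with its exact 95% counting interval, or, at 0 reads, the lower bound from a floor of 3 reads over the group, stands in its place. Those intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

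Gene lists, the groups, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists were proximal tubule, loop of Henle and distal tubule, collecting duct, injured tubule, DNA replication, mitosis, extracellular matrix and myofibroblast, p53 targets, ectonucleotidase and purine salvage, purine synthesis, pyrimidine synthesis, interferon response, inflammatory cytokine and NF-kB, macrophage, neutrophil, lymphocyte, endothelium, podocyte, fatty acid oxidation, oxidative phosphorylation, mineralisation and phosphate handling, NRF2 antioxidant, immediate early and heat shock, adipose tissue, red blood cell and urothelium. Adrenal gland and sex chromosome lists had fewer than 5 genes past the filter and were not tested; adipose tissue and urothelium were below that number in the antibody experiment. Each list was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. With a correlation estimated from the data, none of the lists passed in any of the 5 comparisons, and that adjusted p is given beside each call. In bulk tissue a list that moves is a change in measured RNA, not in cell number.

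The rule for named genes took Enpp1, up to 6 protein-coding genes in each direction with the largest change among those called and with a mean of at least 5 CPM, and up to 4 members of each list with the smallest p; for the difference between effects it took 3 genes in each direction with the smallest p. Some list members were left out. Genes named outside the rule are the platelet genes, the genes read in a single antibody-experiment group and their copies, chosen after values were seen. Havcr1 and Lcn2, named by the rule on adenine, were also given for the libraries labelled knockout after values were seen.

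An adenine score was computed per library as the mean log2 CPM of 3548 adenine-raised genes minus that of 2608 adenine-lowered genes. These were the genes called and changed by at least 1 on the log2 scale in the mean of both adenine groups against chow, a contrast that treats the knockout and wild-type groups alike; Enpp1 was left out. Scores were compared by exact permutation tests of all relabelings. Knockout and antibody effects were correlated across genes, with exact permutation of the antibody and IgG labels.

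Depth differed between the experiments: the knockout libraries held 21164187 to 28350038 assigned reads and the antibody libraries 44080791 to 50813749. The gene test was tested on simulated counts drawn from the real means and library sizes, with 100 genes changed by each of 2 fold sizes. Most simulated genes were thus unchanged, whereas 37.9% to 84.9% of the genes tested were called in the real comparisons. The simulations therefore do not show how the scaling and the test behave when so many genes change. For wild-type adenine against chow, edgeR recovered 85% of genes changed 2-fold and 65% of those changed 1.5-fold among 16688 simulated genes, and called 13 unchanged genes. For knockout against wild type it recovered 93% and 76% among 16737 genes and called 6 unchanged genes. Knockout adenine against chow gave 85% and 64% among 16754 genes, with 4 unchanged genes called. Antibody against IgG gave 81% and 52% among 16209 genes, with 11 unchanged genes called. The difference between effects gave 68% and 51% among 16947 genes, with 6 unchanged genes called. In the order of these comparisons, unchanged genes made up 8.0%, 3.4%, 2.6%, 7.6% and 4.8% of the simulated calls. The share was thus above 5% for wild-type adenine against chow and for antibody against IgG.

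Over the 48 pairs of libraries within groups, no pair agreed within sampling noise: the lowest chi-square per degree of freedom over genes was 4.96, so no library was counted as a repeat of another. Spread between libraries thus exceeded counting noise, and recovery of simulated changes was lower in the deeper antibody experiment, with 4 libraries per group, than for knockout against wild type, with 6.

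The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma voom with quality weights, no filter and a filter at a mean of 1 CPM, a transcript-length offset, the replicate number as a block, leaving out mitochondrial genes, fits of only the 2 groups compared, leaving out each library in turn, a prior count of 0.5, a 4-fold minimum and unit scaling for the score, a minimum of 10 CPM for the correlation, and, for lists, the estimated correlation and fry. Removal of a GC and length trend and list tests with upper-quartile scaling were chosen after seeing the data. Upper-quartile scaling moved the median log2 change of all genes from 0.07 to 0.29 for wild-type adenine against chow, from 0.03 to 0.18 for knockout adenine against chow, from -0.04 to -0.19 for antibody against IgG and from -0.03 to 0.12 for the difference between effects; without scaling, the medians of wild-type adenine and of knockout adenine against chow were 0.71 and 0.58. Changes are relative to the TMM scale throughout. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.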

Results

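Kidney RNA was sequenced from mice on a diet containing adenine, a purine base whose oxidised product is poorly soluble and precipitates in renal tubules. The design asks how loss of ENPP1, an ectonucleotidase that splits extracellular ATP into AMP and pyrophosphate, changes the kidney transcriptome under this diet, and how a monoclonal antibody against human ENPP1 changes it. The knockout experiment held 4 chow-fed mice, 6 wild-type mice on adenine and 6 mice labelled ENPP1 knockout on adenine. The antibody experiment held 4 mice given the antibody and 4 given IgG, all on adenine. Assigned reads per library ranged from 21164187 to 28350038 in the knockout experiment and from 44080791 to 50813749 in the antibody experiment. Mitochondrial genes took 16.9% to 26.7% of them in the former and 20.6% to 30.1% in the latter. Levels are CPM as mean ± SD over the libraries of a group, and log2 changes carry the standard error and adjusted p of edgeR's quasi-likelihood test.

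Enpp1 was examined in every library as a check of the labels. The libraries labelled knockout held 22.7 ± 1.19 CPM of Enpp1 (SD, n = 6, range 21.6 to 24.7) and wild-type adenine libraries 22.0 ± 1.53 CPM (n = 6, range 20.9 to 24.9). The log2 change between them was 0.05 ± 0.051 (SE; 95% interval -0.06 to 0.16, edgeR adjusted p = 0.466). The lower end of the interval was a drop of 4.07%. Upper-quartile scaling turned the sign of this small difference, and its interval reached down to a drop of 8.49%. Enpp1 RNA was thus not reduced beyond these bounds in the libraries labelled knockout. The deleted exons are not given in the labels, and the total per gene would not show a deletion that leaves most of the transcript in place. The genotype of these libraries is therefore given below as labelled. Chow libraries, whose genotype is not given in the labels, held 54.2 ± 2.87 CPM (n = 4). Enpp1 was lower on adenine than on chow in the wild type (log2 change -1.30 ± 0.055, adjusted p = 7.01e-14) and in the libraries labelled knockout (-1.25 ± 0.055, adjusted p = 3.52e-13). In the antibody experiment Enpp1 stood at 8.18 ± 0.751 CPM with IgG (n = 4) and 8.20 ± 6.87 CPM with the antibody (n = 4, range 2.62 to 17.4). This was a log2 change of -0.003 ± 0.47 (adjusted p = 0.997), whose sign turned with RLE scaling. Whether these mice carried human ENPP1, the target named for the antibody, is not given in the labels, and the values are of mouse Enpp1. Enpp1 did not differ past the threshold between the knockout and antibody effects (log2 difference -0.02 ± 0.43, adjusted p = 0.978).

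**Figure D1:**
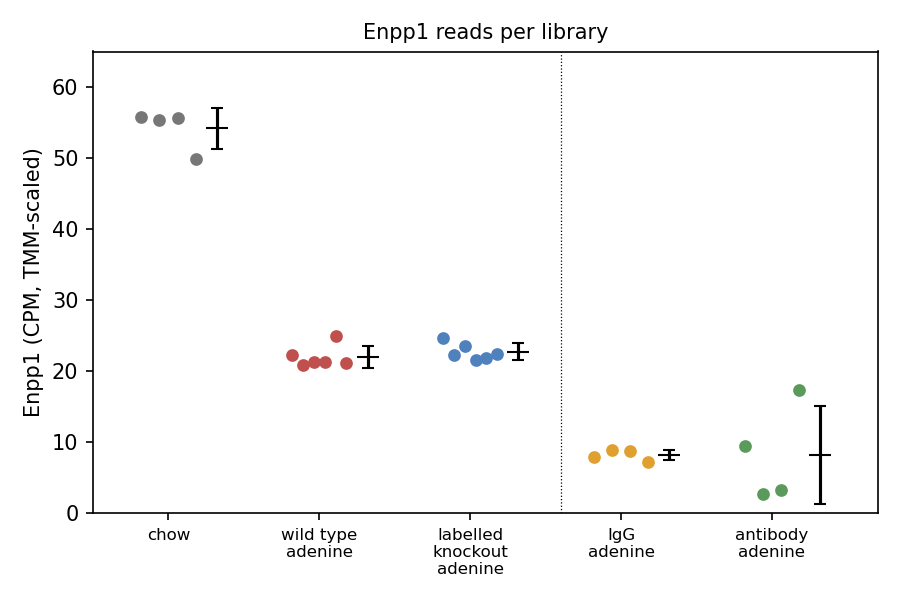
Enpp1 in each of the 24 libraries, in CPM after TMM scaling within each experiment. Points are libraries, bars show the group mean and SD, and the dotted line parts the experiments. The libraries labelled knockout (mean 22.7) lie at the level of wild-type adenine libraries (mean 22.0), both below chow (mean 54.2), and antibody libraries spread from 2.62 to 17.4.

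In wild-type mice on adenine, RNA of the proximal tubule, of the loop of Henle and distal tubule, and of oxidative metabolism was lower than in chow-fed mice, and that of tubular injury, cell division and inflammation was higher, in lists that were called at the preset correlation between genes and not with an estimated one. The genotype of the chow group is not given in the labels, so a difference of genotype from chow may be part of these changes. Aqp1, the water channel of the proximal tubule, fell from 795 ± 141 CPM on chow (n = 4) to 54.9 ± 9.96 on adenine (n = 6), a log2 change of -3.86 ± 0.16 (adjusted p = 5.95e-14). Havcr1, which encodes the kidney injury molecule shed by damaged tubules, rose from 0.613 ± 0.315 to 209 ± 54.7 CPM (log2 change 8.40 ± 0.29, adjusted p = 6.81e-15). Of 16959 genes tested, 7455 were higher and 6944 lower on adenine, 3954 and 3101 of them by at least 2-fold.

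Among protein-coding genes with a mean of at least 5 CPM, the largest falls included those of Dpys, Dnase1, Hpd and globin genes. Dpys, an enzyme of pyrimidine breakdown, fell by 6.28 on the log2 scale (SE 0.34, adjusted p = 1.98e-12). Dnase1, which encodes a secreted nuclease, fell from 1056 ± 27.9 to 15.7 ± 4.53 CPM, and Hpd, an enzyme of tyrosine breakdown, fell from 225 ± 15.0 to 3.37 ± 2.69 CPM. The globin genes Hba-a2, Hbb-bs and Hbb-bt, whose reads can be exchanged between copies, changed by -5.84 ± 0.27, -5.75 ± 0.26 and -5.75 ± 0.23. Among the largest rises, 4 genes had 1 to 3 reads over all 4 chow libraries, so that only a ratio with its counting interval can be given. This ratio was 1280 (229 to 50560) for Sprr2f, an epithelial cornification gene from a cluster of near-identical copies, 730 (131 to 28850) for Arhgap36, 489 (135 to 4036) for the epithelial cytokine gene Il1f6, and 350 (120 to 1700) for Cxcl5, a neutrophil-attracting chemokine. Gm49388, a gene model without an assigned function, had 0 reads over the chow libraries and was at least 235-fold higher on adenine, with an adjusted p of 0.109 by limma voom.

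All 24 proximal tubule genes fell (24 adjusted over the list alone), with a mean log2 change of -2.86, camera adjusted p = 2.82e-07, and adjusted p = 0.355 with an estimated correlation. They included Kap, the androgen-regulated protein of the proximal tubule, which fell from 15800 ± 1041 to 358 ± 173 CPM. Others were the fatty acid transporter Slc27a2 (log2 change -2.14 ± 0.12) and Slc3a1, a subunit of the cystine transporter (-2.23 ± 0.080). Of 15 genes of the loop of Henle and distal tubule, 12 fell and 2 rose (12 and 2 adjusted over the list alone, camera adjusted p = 0.00869). The adjusted p was 0.381 with an estimated correlation. Egf, made in the distal nephron, fell from 1110 ± 81.8 to 95.2 ± 32.6 CPM, and Cldn10, a claudin of the thick ascending limb, changed by -3.03 ± 0.11. All 18 oxidative phosphorylation genes fell (18 adjusted over the list alone, mean log2 change -2.14, camera adjusted p = 8.68e-08). With an estimated correlation this list had adjusted p = 0.304. Sdhb, a subunit of succinate dehydrogenase, changed by -3.04 ± 0.093 and Ndufa9, a subunit of the first respiratory complex, by -2.58 ± 0.077. Of 20 fatty acid oxidation genes, 18 fell and 2 did not pass (18 adjusted over the list alone, camera adjusted p = 1.79e-06, and adjusted p = 0.355 with an estimated correlation). Acadm, a medium-chain acyl-CoA dehydrogenase, fell from 948 ± 75.3 to 126 ± 11.3 CPM, and the carnitine palmitoyltransferase Cpt2 changed by -2.25 ± 0.073.

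Of 20 injured tubule genes, 19 rose and 1 fell (19 and 1 adjusted over the list alone), with a mean log2 change of 2.95, camera adjusted p = 1.2e-06, and adjusted p = 0.304 with an estimated correlation. Lcn2, the iron-carrier-binding lipocalin released by injured epithelium, rose by 5.87 ± 0.15 on the log2 scale, the hyaluronan receptor Cd44 by 4.52 ± 0.16 and the transcription factor Sox4 by 2.43 ± 0.077. The mitosis list rose in 24 of 25 genes (24 adjusted over the list alone, mean log2 change 2.70, camera adjusted p = 1.89e-08, and adjusted p = 0.304 with an estimated correlation). Its members included the proliferation marker Mki67 (4.41 ± 0.12) and the mitotic kinase Cdk1 (2.98 ± 0.11). Of 25 DNA replication genes, 22 rose and 1 fell (22 and 1 adjusted over the list alone, camera adjusted p = 1.93e-05, and adjusted p = 0.304 with an estimated correlation). Uhrf1, which keeps DNA methylation through replication, rose from 1.59 ± 0.315 to 26.1 ± 3.00 CPM.

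All 19 inflammatory cytokine and NF-kB genes rose (19 adjusted over the list alone, mean log2 change 3.21, camera adjusted p = 2e-06, and adjusted p = 0.304 with an estimated correlation). The chemokine Cxcl1 rose from 0.729 ± 0.114 to 90.6 ± 23.7 CPM. Csf1, the growth factor of macrophages, rose by 2.76 ± 0.099 and the adhesion receptor Icam1 by 2.62 ± 0.12. Macrophage markers rose in 18 of 19 genes (18 adjusted over the list alone, camera adjusted p = 1.15e-05, and adjusted p = 0.304 with an estimated correlation). These included the monocyte chemokine receptor Ccr2 (2.98 ± 0.081) and the integrin Itgam (4.15 ± 0.16). Endothelial markers fell in 14 of 16 genes and rose in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 0.00301, and adjusted p = 0.435 with an estimated correlation). The vascular growth factor receptors Kdr and Flt1 changed by -2.51 ± 0.14 and -2.06 ± 0.12. Of 15 podocyte genes, 11 fell and 2 rose (11 and 2 adjusted over the list alone, camera adjusted p = 0.0493, and adjusted p = 0.525 with an estimated correlation). The podocyte call was lost with upper-quartile scaling (adjusted p = 0.0655), with the replicate block (adjusted p = 0.0567) and without chow replicate 3 or 4 or wild-type replicate 1, 2, 3, 4 or 6 (adjusted p from 0.0502 to 0.0747). The red blood cell list fell in 5 of 5 genes (5 adjusted over the list alone, mean log2 change -5.66, camera adjusted p = 0.00698, and adjusted p = 0.355 with an estimated correlation). The extracellular matrix and myofibroblast list moved both ways, with 13 genes higher and 8 lower of 25 (13 and 8 adjusted over the list alone, camera adjusted p = 0.286, and adjusted p = 0.778 with an estimated correlation). Col1a1, a collagen chain, rose by 3.54 ± 0.14 and the metalloproteinase inhibitor Timp1 by 5.85 ± 0.24, whereas Ccn2, a connective tissue growth factor, changed by -1.79 ± 0.067.

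Under the same diet, the libraries labelled knockout were compared with wild type to ask what ENPP1 deletion changes. By the series design the wild-type mice were Cre-negative, so the presence of Cre coincides with the knockout label. An effect of Cre itself cannot be told apart from that of the deletion here. RNA of tubular, oxidative phosphorylation, podocyte and globin genes was higher in the libraries labelled knockout, in which Enpp1 itself was not reduced, and some of the injury, inflammatory and proliferation genes were lower. These lists were called at the preset correlation between genes, and none of them with an estimated correlation. Ass1, the argininosuccinate synthase of the proximal tubule, rose from 112 ± 26.5 CPM in wild type (n = 6) to 821 ± 296 CPM (n = 6), beside 1789 ± 54.1 CPM on chow (n = 4). Its log2 change was 2.88 ± 0.21 (adjusted p = 1.81e-08). Cxcl1 fell from 90.6 ± 23.7 to 41.1 ± 8.19 CPM (log2 change -1.14 ± 0.15, adjusted p = 4.92e-06), beside 0.729 ± 0.114 on chow. Of 16959 genes tested, 4261 were higher and 3612 lower, 549 and 60 by at least 2-fold. The higher genes made up 54.1% of the calls. That share was 40.7% with upper-quartile scaling and 39.3% after removal of a GC and length trend, both on the other side of even.

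At the same minimum of 5 CPM, the largest rises included genes that were lower in wild-type adenine libraries than on chow. Hpd rose by 4.79 ± 0.33 on the log2 scale, Dpys by 4.64 ± 0.34 and Dnase1 by 4.12 ± 0.22. The globin genes rose as well, Hba-a2 from 8.08 ± 3.49 to 148 ± 41.1 CPM, Hbb-bt by 4.00 ± 0.23 and Hbb-bs by 3.88 ± 0.23. Together with Hba-a1 (3.63 ± 0.24), these globins and Alas2, an enzyme of haem synthesis, made up the red blood cell list, which rose in 5 of 5 genes (5 adjusted over the list alone, mean log2 change 3.89, camera adjusted p = 2.89e-06, and adjusted p = 0.364 with an estimated correlation). The largest falls were smaller. Zbtb16, a zinc finger transcription factor, changed by -1.53 ± 0.15 and Pdk4, the kinase that shuts off pyruvate dehydrogenase, by -1.35 ± 0.085. The adhesion receptor Adgrg2 changed by -1.26 ± 0.091, Rims2, a vesicle release protein, by -1.21 ± 0.12, and Jchain, the joining chain of secreted antibodies, by -1.19 ± 0.28 (adjusted p = 0.00185). Pdk4, at 9.85 ± 1.13 CPM, was also below the 23.5 ± 2.25 CPM of chow.

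Of 24 proximal tubule genes, 23 rose (23 adjusted over the list alone), with a mean log2 change of 1.48, camera adjusted p = 4.22e-13, and adjusted p = 0.364 with an estimated correlation. Examples are the gluconeogenic enzyme Fbp1 (2.33 ± 0.20), the inositol oxygenase Miox (2.45 ± 0.21) and Aqp1 (1.66 ± 0.14), which at 173 ± 34.9 CPM stood between wild-type adenine and chow. In the loop of Henle and distal tubule 11 of 15 genes rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.000371, and adjusted p = 0.364 with an estimated correlation). Egf rose from 95.2 ± 32.6 to 324 ± 54.0 CPM and Calb1, a calcium-binding protein of the distal tubule, by 1.03 ± 0.12. All 18 oxidative phosphorylation genes rose (18 adjusted over the list alone, mean log2 change 0.73, camera adjusted p = 4.26e-12, and adjusted p = 0.364 with an estimated correlation). Sdhb rose by 1.13 ± 0.083 and Uqcrc1 by 1.04 ± 0.074. Fatty acid oxidation genes rose in 16 of 20 and fell in 1, which was Pdk4 (16 and 1 adjusted over the list alone, camera adjusted p = 1.36e-06, and adjusted p = 0.384 with an estimated correlation). The peroxisomal enzyme Ehhadh rose by 1.78 ± 0.17 and the thiolase Acaa2 by 1.89 ± 0.14. Podocyte markers rose in 12 of 15 genes (12 adjusted over the list alone, camera adjusted p = 3.14e-05, and adjusted p = 0.364 with an estimated correlation). Podxl rose by 1.30 ± 0.14. Endothelial markers rose in 12 of 16 genes (14 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000463, and adjusted p = 0.439 with an estimated correlation). The changes were 1.10 ± 0.13 for Kdr and 0.89 ± 0.081 for Eng, an endothelial receptor for growth factors of the TGF family. Red blood cell RNA, at a mean log2 change of 3.89, moved in the same direction as each of these lists.

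Injured tubule genes were lower in 10 of 20 and higher in 0 (10 and 0 adjusted over the list alone, mean log2 change -0.29, camera adjusted p = 0.00118, and adjusted p = 0.439 with an estimated correlation). Sox9, a transcription factor of regenerating tubule, changed by -0.91 ± 0.11, Cd44 by -0.51 ± 0.097 and Sox4 by -0.50 ± 0.061. Havcr1, by contrast, stood at 209 ± 54.7 CPM in wild type and 211 ± 31.9 in the libraries labelled knockout. Lcn2 stood at 288 ± 30 CPM in wild type and 259 ± 42.6 in the libraries labelled knockout. Inflammatory cytokine and NF-kB genes were lower in 12 of 19 (13 adjusted over the list alone, mean log2 change -0.44, camera adjusted p = 0.000151, and adjusted p = 0.364 with an estimated correlation). They included Icam1 (-0.69 ± 0.091), Csf1 (-0.51 ± 0.074) and Nfkbia, the NF-kB inhibitor that NF-kB itself induces (-0.42 ± 0.046). DNA replication genes fell in 8 of 25 and rose in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00789, and adjusted p = 0.439 with an estimated correlation). The helicase subunit Mcm7 changed by -0.40 ± 0.048 and Uhrf1 by -0.48 ± 0.087. The member that rose was the thymidine kinase Tk1 (0.25 ± 0.067), whose call ended after removal of a GC and length trend (adjusted p = 0.148). Mitosis genes fell in 9 of 25 (7 adjusted over the list alone, mean log2 change -0.19, camera adjusted p = 0.0188, and adjusted p = 0.439 with an estimated correlation). Ndc80, a kinetochore protein, changed by -0.40 ± 0.099. Cenpf, also of the kinetochore, fell by 0.19 (SE 0.059, adjusted p = 0.0135) but turned to 0.02 with a transcript-length offset. The mitosis call was lost without wild-type replicate 3 (adjusted p = 0.0520).

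Matrix, immune and interferon genes did not share a direction. The extracellular matrix and myofibroblast list rose in 11 of 25 genes and fell in 1 (11 and 1 adjusted over the list alone, mean log2 change 0.20, camera adjusted p = 0.0125, and adjusted p = 0.553 with an estimated correlation). This call was lost without knockout replicate 5 (adjusted p = 0.0752). Its members included the proteoglycan Bgn (0.52 ± 0.058), the pericyte receptor Pdgfrb (0.52 ± 0.059) and the collagen chain Col5a1 (0.52 ± 0.083). Macrophage markers were lower in 2 of 19 genes (1 adjusted over the list alone) and the list was not called (mean log2 change -0.14, camera adjusted p = 0.191, and adjusted p = 0.666 with an estimated correlation). The lysosomal marker Cd68 changed by -0.40 ± 0.080. The interferon response list was lower in 4 of 26 genes and higher in 1 (4 and 1 adjusted over the list alone) and was not called (mean log2 change -0.10, camera adjusted p = 0.149, and adjusted p = 0.679 with an estimated correlation). The RNA sensor Ddx58 changed by -0.45 ± 0.055 and the antiviral gene Rsad2 by 0.42 ± 0.084. Without wild-type replicate 5, both lists passed (adjusted p = 0.0493 for macrophage, 0.0494 for interferon response). Of 15 lymphocyte genes, 0 passed the edgeR test, also adjusted over the list alone. The mean log2 change was 0.03, the median -0.004 and the camera direction lower (adjusted p = 0.962, and adjusted p = 0.967 with an estimated correlation).

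The adenine score summed these shifts over genes higher or lower on adenine than on chow. It was -4.94 ± 0.17 on chow (n = 4), -1.14 ± 0.073 in wild type on adenine (n = 6) and -2.02 ± 0.20 in the libraries labelled knockout (n = 6). The difference was -0.88 (exact permutation p = 0.00216 over 924 relabelings, the smallest they can give). Each of the 6 libraries labelled knockout lay below each of the 6 wild-type libraries, and the difference came to -23.1% of the distance of 3.80 between wild-type adenine and chow. Of 3548 adenine-raised genes, 1421 were lower and 44 higher in the libraries labelled knockout. Of 2608 adenine-lowered genes, 2192 were higher and 7 lower.

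**Figure D2:**
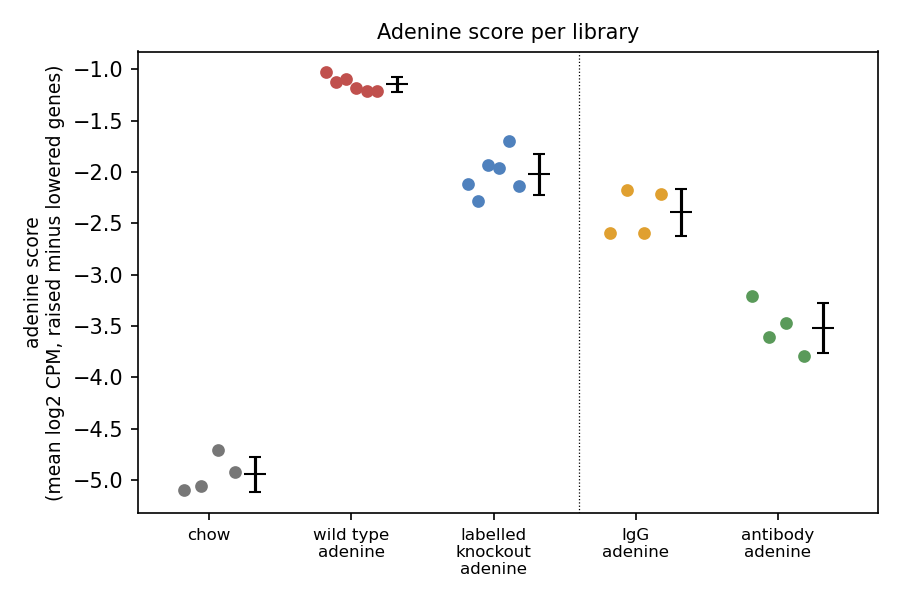
Adenine score of each of the 24 libraries, the mean log2 CPM of adenine-raised genes minus that of adenine-lowered genes. Points are libraries, bars show the group mean and SD, and the dotted line parts the experiments, which were scaled separately. The libraries labelled knockout (mean -2.02) lie between wild-type adenine (-1.14) and chow (-4.94), and the antibody libraries (-3.52) lie below IgG (-2.39).

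Adenine-fed mice labelled knockout were also set against chow, to ask how far they differ from mice without the diet. Injured tubule genes rose in 19 of 20 and fell in 1 (19 and 1 adjusted over the list alone, mean log2 change 2.67, camera adjusted p = 2.1e-07, and adjusted p = 0.264 with an estimated correlation). Mitosis genes rose in 24 of 25 (24 adjusted over the list alone, 2.51, camera adjusted p = 6.93e-10, and adjusted p = 0.185 with an estimated correlation). Inflammatory cytokine and NF-kB genes rose in 18 of 19 (18 adjusted over the list alone, 2.77, camera adjusted p = 1.61e-06, and adjusted p = 0.264 with an estimated correlation). Proximal tubule genes fell in 22 of 24 (23 adjusted over the list alone, -1.38, camera adjusted p = 5.46e-05, and adjusted p = 0.498 with an estimated correlation). Oxidative phosphorylation genes fell in 18 of 18 (18 adjusted over the list alone, -1.42, camera adjusted p = 1.97e-07, and adjusted p = 0.327 with an estimated correlation). The podocyte list was not called (8 lower and 4 higher of 15, the same counts adjusted over the list alone, camera adjusted p = 0.581, and adjusted p = 0.852 with an estimated correlation). Of 16959 genes, 6815 were higher and 6765 lower than on chow, 3158 and 1925 by at least 2-fold. Both adenine groups shared 6530 higher and 6379 lower calls against chow, beside 2996 and 2770 for independent lists of those sizes. Simulated unchanged groups against the same chow libraries shared a mean of 0.05 and 0 calls over 20 simulations, since they gave hardly any calls, and 123 and 107 genes at unadjusted p below 0.05. With the chow libraries split into 2 and 2, so that no control was shared, 5651 and 5785 calls were shared in the first assignment (2534 and 2448 for independent lists) and 5792 and 5880 in the other (2582 and 2475).

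In the separate experiment, the antibody was compared with IgG on adenine. Proximal tubule RNA was higher and the RNA of cell division, matrix, interferon response and macrophages lower with the antibody, in lists called at the preset correlation between genes and not with an estimated one (adjusted p = 0.425 for each). Lrp2, which encodes the endocytic receptor megalin, rose from 292 ± 71.4 CPM with IgG (n = 4) to 1312 ± 241 with the antibody (n = 4), a log2 change of 2.17 ± 0.19 (adjusted p = 4.36e-05). Col1a2, a collagen chain, fell from 162 ± 50.3 to 51.3 ± 12.9 CPM (log2 change -1.66 ± 0.22, adjusted p = 0.000165), and the mitotic marker Mki67 from 58.4 ± 6.32 to 29.9 ± 6.03 (-0.96 ± 0.13, adjusted p = 0.000170). Of 16404 genes tested, 4467 were higher and 4601 lower, 669 and 1190 by at least 2-fold. The higher genes were 49.3% of the calls and 31.1% with upper-quartile scaling.

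Among the largest rises, Abhd4, a phospholipid hydrolase, changed by 4.42 ± 0.73, with a spread close to its mean in the antibody group (23.8 ± 22.0 CPM). Hpd rose by 3.94 ± 0.43, Dpys by 3.69 ± 0.38 and Slc7a13, an amino acid transporter of the late proximal tubule, by 3.63 ± 0.47. Cyp2d12 (5.56 ± 0.64) and Ces1g (4.71 ± 0.54), of drug-metabolising and carboxylesterase families with close copies, also rose. The largest falls included the urea transporter Slc14a2 (-2.69 ± 0.57, adjusted p = 0.00235), the adhesion receptor Adgra1 (-2.16 ± 0.37) and Ltbp2, a matrix protein of elastic fibres (-2.12 ± 0.32). Ugt1a5 (-2.50 ± 0.59) and Vmn2r113 (-2.41 ± 0.41) also fell, and their reads can be exchanged with related copies. Slc14a2 and Ugt1a5 had a spread close to their mean in the IgG group (16.6 ± 13.3 and 8.99 ± 7.7 CPM). Rpl9-ps6, a copy of a ribosomal protein gene, held 6464 reads over the IgG libraries and 0 over the antibody libraries, at least 1680-fold lower.

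All 24 proximal tubule genes rose (24 adjusted over the list alone, mean log2 change 1.75, camera adjusted p = 1.39e-11, and adjusted p = 0.425 with an estimated correlation). Among them were Cubn, the partner receptor of megalin (1.79 ± 0.13), Aqp1 (1.73 ± 0.15) and Slc3a1 (1.06 ± 0.094). In the loop of Henle and distal tubule 13 of 15 genes rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.000293, and adjusted p = 0.425 with an estimated correlation). Egf rose from 49.5 ± 28.6 to 367 ± 158 CPM and Slc12a3, the thiazide-sensitive cotransporter, by 0.99 ± 0.14. Fatty acid oxidation genes rose in 18 of 20 (18 adjusted over the list alone, mean log2 change 1.05, camera adjusted p = 5.06e-07, and adjusted p = 0.425 with an estimated correlation). The electron carrier enzyme Etfdh rose by 1.37 ± 0.12. Oxidative phosphorylation genes rose in 12 of 18 (12 adjusted over the list alone, 0.67, camera adjusted p = 3.25e-06, and adjusted p = 0.425 with an estimated correlation), including Sdha (1.28 ± 0.12) and Ndufs1 (1.04 ± 0.086).

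Mitosis genes fell in 24 of 24 (24 adjusted over the list alone, mean log2 change -0.99, camera adjusted p = 2.2e-08, and adjusted p = 0.425 with an estimated correlation). Ube2c, a ubiquitin enzyme of mitotic exit, changed by -1.31 ± 0.17 and Birc5, the survivin gene, by -1.24 ± 0.16. DNA replication genes fell in 21 of 25 (21 adjusted over the list alone, -0.60, camera adjusted p = 6.97e-06, and adjusted p = 0.425 with an estimated correlation). Uhrf1 changed by -1.01 ± 0.16 and the DNA ligase Lig1 by -0.80 ± 0.11. Extracellular matrix and myofibroblast genes fell in 23 of 25 (23 adjusted over the list alone, -1.08, camera adjusted p = 4.75e-07, and adjusted p = 0.425 with an estimated correlation). Col3a1 changed by -1.51 ± 0.19 and Timp1 by -1.47 ± 0.17. Interferon response genes fell in 22 of 26 (24 adjusted over the list alone, -0.92, camera adjusted p = 8.98e-07, and adjusted p = 0.425 with an estimated correlation). These included Ifit1 (-1.22 ± 0.18), Usp18 (-1.13 ± 0.16) and Rsad2 (-1.03 ± 0.14). Macrophage markers fell in 18 of 19 (18 adjusted over the list alone, -1.24, camera adjusted p = 3.25e-06, and adjusted p = 0.425 with an estimated correlation). The complement gene C1qb changed by -1.44 ± 0.21, the mannose receptor Mrc1 by -1.36 ± 0.20 and Cd68 by -0.89 ± 0.14. Injured tubule genes fell in 16 of 20 (16 adjusted over the list alone, -0.64, camera adjusted p = 7.71e-05, and adjusted p = 0.425 with an estimated correlation). Members that fell included the calcium-binding S100a6 (-1.65 ± 0.12), Cd44 (-0.78 ± 0.10) and the adhesion molecule Vcam1 (-0.59 ± 0.082). Inflammatory cytokine and NF-kB genes fell in 14 of 19 (16 adjusted over the list alone, -0.75, camera adjusted p = 0.000347, and adjusted p = 0.425 with an estimated correlation). The cytokine gene Il1b changed by -1.27 ± 0.22 and Nfkbia by -0.84 ± 0.10. The red blood cell list was not called: 0 of 5 genes passed edgeR's test, also adjusted over the list alone (mean log2 change 0.39, camera adjusted p = 0.337, and adjusted p = 0.661 with an estimated correlation). Hba-a1 stood at 3.58 ± 1.02 CPM with IgG and 4.79 ± 1.48 with the antibody.

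The adenine score, from genes chosen in the other experiment, was -2.39 ± 0.23 with IgG (n = 4) and -3.52 ± 0.25 with the antibody (n = 4). The difference was -1.13 (exact permutation p = 0.0286 over 70 relabelings, the smallest they can give). Each of the 4 antibody libraries lay below each of the 4 IgG libraries. Of the adenine-raised genes tested in this experiment, 1861 were lower and 71 higher with the antibody. Of the adenine-lowered genes, 1580 were higher and 141 lower.

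**Figure D3:**
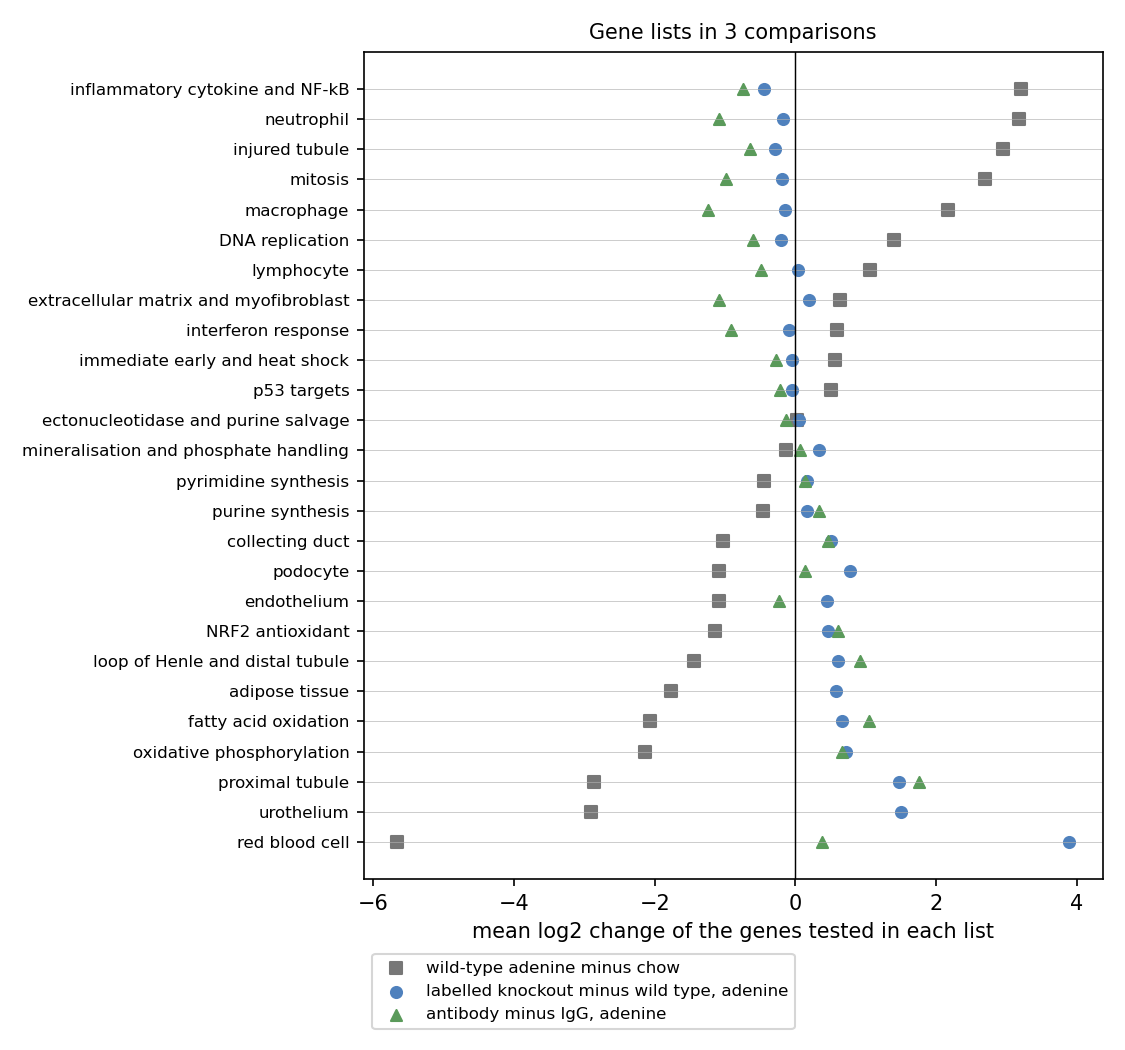
Mean log2 change of the genes tested in each gene list (horizontal axis), for wild-type adenine minus chow (squares), libraries labelled knockout minus wild type on adenine (circles) and antibody minus IgG (triangles). Lists are ordered by the squares, and adipose tissue and urothelium have no triangle. Proximal tubule lies at -2.86, 1.48 and 1.75, mitosis at 2.70, -0.19 and -0.99, and red blood cell at -5.66, 3.89 and 0.39.

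Whether the effect in the libraries labelled knockout differed from the antibody effect was tested directly over the 20 adenine libraries. The matrix genes Col6a3, a collagen chain, and Nid1, a basement membrane linker, rose with the knockout label and fell with the antibody. Col6a3 stood at 23.8 ± 3.01 CPM in wild type (n = 6), 44.4 ± 4.25 in the libraries labelled knockout (n = 6), 17.5 ± 4.45 with IgG (n = 4) and 7.96 ± 1.47 with the antibody (n = 4). The log2 difference between its effects was 2.04 ± 0.19 (adjusted p = 8.74e-07). The difference was 1.38 ± 0.13 for Nid1 and 2.74 ± 0.26 for Cdh13, a cadherin anchored in the outer membrane. In the other direction, the deubiquitinase Usp24 stood at 169 ± 12.5 CPM in wild type, 128 ± 1.92 in the libraries labelled knockout, 129 ± 4.01 with IgG and 216 ± 5.08 with the antibody (difference -1.14 ± 0.070, adjusted p = 3.96e-09). The differences were -0.84 ± 0.062 for the galectin Lgals8 and -0.94 ± 0.080 for Chdh, the choline dehydrogenase. Of 17113 genes tested, 2788 had a higher and 3695 a lower knockout effect. The higher ones were 43.0% of the calls and 69.1% with upper-quartile scaling.

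These differences are signed, so a knockout effect above the antibody effect can be a smaller fall. The knockout effect lay above the antibody effect in 21 of 25 extracellular matrix and myofibroblast genes (22 adjusted over the list alone, mean log2 difference 1.20, camera adjusted p = 1.14e-13, and adjusted p = 0.387 with an estimated correlation). It was also above it in 22 of 25 mitosis genes (23 adjusted over the list alone, 0.72, camera adjusted p = 3.59e-10, and adjusted p = 0.387 with an estimated correlation) and 17 of 19 macrophage genes (17 adjusted over the list alone, 1.02, camera adjusted p = 6.31e-08, and adjusted p = 0.387 with an estimated correlation). The same held in 17 of 26 interferon response genes, with 1 lower (19 and 1 adjusted over the list alone, 0.74, camera adjusted p = 5.62e-07, and adjusted p = 0.387 with an estimated correlation), and in 5 of 5 red blood cell genes (5 adjusted over the list alone, 3.46, camera adjusted p = 1.24e-05, and adjusted p = 0.387 with an estimated correlation). With the antibody, the mean log2 changes were -0.99 for mitosis, -1.24 for macrophage and -0.92 for interferon response. With the knockout label they were smaller, at -0.19, -0.14 and -0.10. The matrix list had means of -1.08 with the antibody and 0.20 with the knockout label. The proximal tubule list was not called (8 lower of 24, 8 adjusted over the list alone, mean log2 difference -0.35, camera adjusted p = 0.187, and adjusted p = 0.761 with an estimated correlation). It passed with upper-quartile scaling (camera adjusted p = 0.0314), at a smaller mean log2 difference of -0.20. Across the 16076 genes tested in both experiments, the effects correlated with Pearson's r = 0.563 and Spearman's rho = 0.555. Genes are not independent replicates, and by exact permutation of the antibody and IgG labels the p was 0.0857 for r and 0.114 for rho, and another relabeling reached r = 0.58, above the real one. In these genes 2579 calls were higher in both and 1862 lower in both, beside 1138 and 999 for independent lists. In opposite directions, 320 were higher with the knockout label and lower with the antibody and 227 the reverse. The experiments also differed in the Y-linked genes of the sex chromosome list. In CPM of all assigned reads, without TMM scaling, Ddx3y lay between 0.142 and 0.561 in the knockout experiment and between 71.1 and 100.3 in the antibody experiment, and Eif2s3y between 0 and 0.142 and between 58.5 and 111.7. On the same scale, Kdm5d and Uty were read in both, at 7.34 to 14.7 and 0.801 to 5.53 CPM in the former and 31.4 to 52.1 and 29.4 to 49.1 CPM in the latter. The range of each of these genes thus did not overlap between the experiments, which is what mice of unlike sex would give, although the labels give no sex. Such a difference would coincide with the experiments. It cannot be told apart from the difference between effects, and neither can the unlike depth of the experiments.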

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

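Of the tests below, the platelet test and the splits of the samples were chosen before their results were seen; those on Enpp1, on mixing with chow RNA and on genes read in a single group, and the rule that made the platelet test void, were chosen after. Enpp1 RNA stood at the same level in the libraries labelled knockout and in wild type. Libraries of 2 genotypes, with and without Enpp1 RNA, swapped or mixed between groups would leave some of the 12 adenine libraries far below their median. The lowest held 94.4% of it, which argues against such a swap. Genotypes that both keep countable Enpp1 RNA could be swapped without a trace in these values, so such a swap was not tested. A deletion that leaves most of the transcript countable cannot be told apart from an unrecombined gene here, because the removed exons are not in the labels; the lower 95% bound of the log2 change was -0.06 with TMM and -0.13 with upper-quartile scaling. A single transcript took 86.3% to 89.3% of the Enpp1 reads in the 6 libraries labelled knockout, 79.1% to 85.6% in the 6 wild-type adenine libraries and 93.7% to 96.2% on chow, a shift toward chow that does not settle which exons were read. Both stay open, and no biological explanation was tested.

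Globin and Alas2 RNA was higher in the libraries labelled knockout than in wild type on adenine (mean log2 change of the red blood cell list 3.89, SE 0.30, exact permutation p = 0.00216, n = 6 each). More blood left in the tissue stays open: 6 platelet genes had a mean log2 change of 0.002 (SE 0.16, exact permutation p = 0.989, n = 6 each), but this list changed by 0.365 from chow to wild-type adenine while the red blood cell list changed by -5.66, so it did not follow globin RNA and the test was void, and its most abundant genes, Itga2b and Pf4, went from 8.14 to 9.49 (edgeR adjusted p = 0.0449) and from 2.03 to 2.65 CPM (adjusted p = 0.0502). Chow kidney RNA mixed into the libraries labelled knockout as the whole cause would move every list by the same share of the distance from wild type to chow. In 6 of 6 libraries, however, the mitosis list covered a smaller share than the red blood cell list. The mean gap was 15.4 percentage points (SD 4.10, exact sign-flip p = 0.0312, the smallest that 6 libraries can give). This pair was picked from many lists after values were seen, so the p is not that of a pair fixed beforehand. The shares are medians over the 24 mitosis and 5 red blood cell genes called and changed at least 2-fold between wild-type adenine and chow. All libraries were measured against the same wild-type and chow means, so this p covers only the spread among the libraries labelled knockout. An earlier form of that test, whose bound of 5% was not passed because 25 of 609 genes called at 2-fold (4.11%) went beyond both groups, did not exclude mixing and was replaced after both values were seen; without the 2-fold minimum, 293 higher and 354 lower of the 7873 called genes went beyond both groups. A part of the shift from mixing stays open, although the median share covered by a list ran from -4.70% for extracellular matrix, 1.21% for lymphocyte and 12.8% for macrophage over 30.7% for red blood cells to 39.0% for podocyte and 49.5% for immediate early genes; less injury with the knockout label may also account for it, as a hypothesis that was not tested.

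In the antibody experiment, 6 genes had at least 20 reads in every library of a group and at most 3 in every library of the other. Other splits of the 8 libraries gave at most 2 such genes, and knockout against wild type gave 0. The knockout experiment had lower depth and more libraries per group under the same read bounds, so its 0 is not a like comparison. Gm14117, Gm12070, Sms-ps, Gm8203 and Gm49383 were read with the antibody and Rpl9-ps6 with IgG, and each shares 65.1% to 100% of its 31-base words with a more abundant gene (Atpaf1, Gapdh, Sms, Tmcc1, Dnaaf2 and Rpl9). Reads moved between copies could account for them, but the test was void: summed with those copies, their median absolute log2 change was 0.404, and the sum follows the copy, which was more abundant in 6 of 6 pairs. Rpl9 stood at 258 CPM with IgG and 259 with the antibody while Rpl9-ps6 went from 31.31 ± 11.99 (SD, n = 4) to 0. A genetic difference between the mice of the groups, such as a strain background that differs at these 6 loci, is a candidate explanation that cannot be told apart from the treatment, because mice and groups coincide.

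Other splits of the samples were refitted to ask whether chance can be excluded for the counts of genes. For wild-type adenine against chow 1 of 100 splits, the real one, gave as many as 14399 genes (highest other 9090), for knockout against wild type 1 of 100 gave 7873 (highest other 4508), and for knockout adenine against chow 1 of 100 gave 13580 (highest other 9500). For antibody against IgG 1 of 35 splits gave 9068 genes; by edgeR the highest other count was 0. For the difference between effects 2 of 100 splits, the real one included, gave 6483 genes or more, and the other gave 8472. That split exchanged antibody and IgG in full and kept 8 of the other 12 libraries in their own group, so that it followed the structure of the samples and summed the effects it should subtract. Chance is excluded at these shares for knockout against wild type, for both comparisons with chow and for antibody against IgG, where 1 of 35 is the smallest share possible. For the difference between effects, the splits exchanged labels within each experiment and so removed both effects along with their difference. They therefore cannot exclude chance for that difference.

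Single libraries stood apart from the others of their group in 28 of 478 groups of values (5.86%), where the same bound picked 4.92% of simulated groups of 4 normal values and 5.03% of groups of 6. Wild-type replicate 5 was high in Enpp1 (24.9 CPM) and Slc34a3 (15.1 CPM) and low in the injured tubule list (mean log2 CPM 7.07), Sox4 (194 CPM) and Cd68 (16.4 CPM). Wild-type replicate 3 was low in the matrix list (4.68) and Col5a1 (11.7 CPM) and high in the NRF2 list (5.38), and replicate 1 was high in Cxcl5 (21.9 CPM) and low in Cpt2 (30.9 CPM). Among the libraries labelled knockout, replicate 1 was high in its mitochondrial share (22.2%) and low in Xdh (82.0 CPM), and replicate 2 was low in Bgn (158 CPM) and Pdgfrb (46.0 CPM). Chow replicate 4 was low in Enpp1 (49.9 CPM), replicate 3 low in the interferon list (3.45) and high in Arhgap36 (0.0495 CPM), and replicate 2 high in Sprr2f (0.0524 CPM) and low in Cxcl5 (0 CPM) and Sox9 (0.681 CPM). Antibody replicate 4 was low in genes with a read (20004), the p53 list (4.07) and the neutrophil list (-0.64) and high in Slc7a13 (295 CPM); replicate 1 was high in the mitosis list (2.73), Mki67 (38.9 CPM) and Uhrf1 (18.0 CPM), and replicate 2 low in the endothelial list (2.54).

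The test of the knockout effect minus the antibody effect called 2788 genes with a positive and 3695 with a negative difference, with Col6a3 at 2.04, Cdh13 at 2.74, Nid1 at 1.38, Usp24 at -1.14, Lgals8 at -0.84 and Chdh at -0.94. It also called 14 lists, whose mean log2 differences were 1.20 for extracellular matrix, 0.72 for mitosis, 1.02 for macrophage, 0.74 for interferon response, 3.46 for red blood cell, 2.74 for urothelium (a list with fewer than 5 genes past the filter in the antibody experiment, so that this value rests on genes near the floor there), 0.60 for endothelium, 0.56 for podocyte, 0.47 for lymphocyte, 0.80 for neutrophil, 0.32 for DNA replication, 0.27 for injured tubule, -0.24 for purine synthesis and -0.46 for fatty acid oxidation; none passed with an estimated correlation. The experiments differ in depth and in Y-linked RNA, and the labels give no sex, so the interventions alone need not account for these values.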

How the results depend on the processing

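Of the alternatives, the removal of a GC and length trend and the list tests with upper-quartile scaling were chosen after the results were seen. The counts of genes called kept within 1.5 times their value under every alternative, apart from the difference between effects, where upper-quartile scaling gave 4495 higher and 2014 lower against 2788 and 3695; both counts rest on the scale, and the cause was not tested. Without 1 library at a time, higher and lower calls ranged from 7348 to 7569 and 6695 to 6914 for wild-type adenine against chow, 3956 to 4312 and 3228 to 3650 for knockout against wild type, 6695 to 6955 and 6430 to 6788 for knockout adenine against chow, 4025 to 4448 and 3749 to 4598 for antibody against IgG, and 2397 to 3003 and 3145 to 3827 for the difference between effects. The adenine score difference stayed between -0.94 and -0.83 for the knockout label (exact p at most 0.00216) and between -1.23 and -1.03 for the antibody (at most 0.0286).

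The number of lists called was 15, 15, 14, 15 and 14 in the order of those comparisons. It was 0 in each with an estimated correlation, and 25, 18, 24, 19 and 16 with fry, which does not set a list against other genes. For knockout against wild type, the lists gained with fry were pyrimidine synthesis (fry adjusted p = 0.000383), mineralisation (8.28e-05) and urothelium (0.0164). For antibody against IgG, they were p53 targets (fry adjusted p = 0.0258), pyrimidine synthesis (0.047), lymphocyte (0.0318) and endothelium (0.0492). Over all comparisons, 9 gene-list directions turned in refits of the full set, all with upper-quartile scaling: mineralisation 0.094 for wild-type adenine against chow; ectonucleotidase -0.014 and lymphocyte -0.029 for knockout against wild type; pyrimidine synthesis -0.012, podocyte -0.011 and mineralisation -0.087 for antibody against IgG; and collecting duct 0.13, pyrimidine synthesis 0.095 and oxidative phosphorylation 0.13 for the difference between effects. None of these lists was called as reported. For that difference, the mean of the collecting duct list turned without knockout replicate 4, wild-type 1 or 4, antibody 1 or IgG 2 (from -0.155 to 0.113 over all libraries), and that of oxidative phosphorylation without knockout 5, wild-type 4, antibody 2 or 4 or IgG 2 or 4 (from -0.077 to 0.031). The injured tubule call there was lost without knockout 4, wild-type 5 or antibody 4 (adjusted p = 0.0526, 0.0809 and 0.114), with upper-quartile scaling (0.0547) and with fry (0.133). The mean of that list, 0.274 as reported, was 0.242, 0.221 and 0.168 without those libraries and 0.429 with upper-quartile scaling. The neutrophil, lymphocyte and urothelium calls of that difference were lost with upper-quartile scaling (adjusted p = 0.0780, 0.0780 and 0.0563). Lists not called there that passed were loop of Henle and distal tubule with upper-quartile scaling (0.0314), with fry (0.0468) and without knockout 1, wild-type 3, antibody 1 or 3 or IgG 1 or 3 (0.0155 to 0.0492), and NRF2 with upper-quartile scaling (0.0435), with fry (0.0181) and without IgG 1 (0.0224). Upper-quartile scaling brought the means of these lists nearer to none, from -0.393 to -0.238 for loop of Henle and distal tubule and from -0.22 to -0.065 for NRF2. Proximal tubule also passed with that scaling (0.0314), at -0.197 against -0.353 as reported. Collecting duct passed without IgG 1 (0.0496), and adipose tissue with fry (0.0468) and without antibody 4 (0.0436). The cause was not tested.

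Among named genes, Cenpf turned to 0.021 with the transcript-length offset. Enpp1, not called between the groups concerned, turned to -0.017 with upper-quartile scaling for the knockout label; for the antibody it turned to 0.014 with RLE scaling, 0.02 with DESeq2 and 0.22 with the length offset, and ranged from -0.673 to 0.298 without single libraries; and for the difference between effects it turned to 0.13 with upper-quartile scaling, 0.76 with voom, 0.02 without mitochondrial genes, 0.14 with the replicate block, 0.10 after removal of the GC and length trend, and ranged from -0.315 to 0.659 without single libraries. The cause was not tested.

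Replicate numbers did not pair the libraries: the correlations of same-numbered deviations ran from -0.14 to 0.07 over the 6 pairs labelled knockout and wild type and from -0.08 to -0.01 over the 4 antibody and IgG pairs. With the replicate block, 14100, 7522, 13241, 8270 and 5888 genes were called, of which 14029, 7369, 13137, 8149 and 5822 were among those reported. The antibody score difference of -1.13 kept its size with the replicate block but had exact sign-flip p = 0.125, the smallest that 4 pairs can give. Genes near 3 reads per group rest on few reads, and an effect of depth on them was not tested.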

Other observations

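Lists outside the comparisons above covered nucleotide handling, mineral handling and antioxidant defence. Of 21 ectonucleotidase and purine salvage genes, adenine raised 10 and lowered 8 in wild type (10 and 8 adjusted over the list alone, camera adjusted p = 0.960, and adjusted p = 0.957 with an estimated correlation). Adk, the adenosine kinase, fell from 147 ± 9.06 (SD, n = 4) to 18.5 ± 1.33 CPM (n = 6). Ampd2, an AMP deaminase, rose by 1.35 ± 0.062 (SE) on the log2 scale and Xdh, which makes uric acid, by 1.07 ± 0.057. In the libraries labelled knockout, whose Enpp1 was not reduced, 5 of these genes were higher and 6 lower than in wild type (6 and 6 adjusted over the list alone, mean log2 change 0.05 but median -0.07, camera adjusted p = 0.794, and adjusted p = 0.783 with an estimated correlation). Adk rose by 1.17 ± 0.15 and the phosphatase Alpl by 0.62 ± 0.12, and the ectonucleotidase Entpd2 changed by -0.56 ± 0.071 and Xdh by -0.33 ± 0.048. With the antibody, 2 of 20 were higher and 6 lower than with IgG (2 and 4 adjusted over the list alone, camera adjusted p = 0.415, and adjusted p = 0.623 with an estimated correlation). Enpp3, the relative of Enpp1, rose by 0.83 ± 0.081, Adk by 1.19 ± 0.13, and the adenosine receptor Adora1 changed by -0.98 ± 0.15. Purine synthesis genes were lower in 7 and higher in 2 of 12 on adenine (7 and 2 adjusted over the list alone, camera adjusted p = 0.0690, and adjusted p = 0.410 with an estimated correlation). They were higher in 7 of 12 with the knockout label (7 adjusted over the list alone, camera adjusted p = 0.0436, and adjusted p = 0.439 with an estimated correlation) and higher in 8 of 12 with the antibody (8 adjusted over the list alone, camera adjusted p = 0.00258, and adjusted p = 0.425 with an estimated correlation). The call with the knockout label was lost with upper-quartile scaling (adjusted p = 0.0673) and without knockout replicate 4, 5 or 6 or wild-type replicate 5 (adjusted p from 0.0507 to 0.0636). Pyrimidine synthesis was not called in these comparisons (camera adjusted p = 0.104, 0.0933 and 0.274, and adjusted p = 0.435, 0.439 and 0.615 with an estimated correlation), with 8 lower and 3 higher, 5 higher and 2 lower, and 4 higher and 2 lower of 11, the same counts adjusted over the list alone.

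Antioxidant genes of the NRF2 list fell in 9 and rose in 1 of 12 on adenine (9 and 1 adjusted over the list alone, camera adjusted p = 0.00708, and adjusted p = 0.304 with an estimated correlation). Nqo1, a quinone reductase, fell from 67.6 ± 3.14 (SD, n = 4) to 10.1 ± 0.377 CPM (n = 6). The NRF2 list rose in 8 genes and fell in 1 with the knockout label (8 and 1 adjusted over the list alone, camera adjusted p = 0.00789, and adjusted p = 0.364 with an estimated correlation). With the antibody it rose in 11 and fell in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.000609, and adjusted p = 0.425 with an estimated correlation). There, the glutathione synthesis gene Gclm changed by 0.74 ± 0.096 (SE) and the malic enzyme Me1 by 0.87 ± 0.11. Mineralisation and phosphate handling genes were not called, with 7 higher and 7 lower of 17 on adenine (7 and 7 adjusted over the list alone, camera adjusted p = 0.814, and adjusted p = 0.875 with an estimated correlation). With the knockout label 9 were higher and 3 lower (9 and 4 adjusted over the list alone, camera adjusted p = 0.104, and adjusted p = 0.439 with an estimated correlation), and with the antibody 6 and 4 (6 and 5 adjusted over the list alone, mean log2 change 0.07 but median -0.12, camera adjusted p = 0.587, and adjusted p = 0.661 with an estimated correlation). The phosphate cotransporter Slc34a3 rose by 2.28 ± 0.19 with the knockout label and by 2.14 ± 0.27 with the antibody. Abcc6, a transporter behind extracellular pyrophosphate, rose by 1.12 ± 0.10 with the knockout label and by 0.81 ± 0.13 with the antibody. Kl, the klotho co-receptor, rose from 101 ± 19.9 to 287 ± 55.6 CPM (SD, n = 4 each) with the antibody.

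Other tissue and stress lists were as follows. Collecting duct genes were lower in 10 and higher in 2 of 15 on adenine (9 and 2 adjusted over the list alone, camera adjusted p = 0.0690, and adjusted p = 0.410 with an estimated correlation). They were higher in 9 with the knockout label (9 adjusted over the list alone, camera adjusted p = 0.0115, and adjusted p = 0.364 with an estimated correlation), and higher in 8 and lower in 1 with the antibody (10 and 1 adjusted over the list alone, camera adjusted p = 0.0106, and adjusted p = 0.528 with an estimated correlation). Neutrophil genes rose in 7 of 7 on adenine (7 adjusted over the list alone, camera adjusted p = 0.00967, and adjusted p = 0.304 with an estimated correlation). Of these, 1 of 7 was lower with the knockout label (1 adjusted over the list alone, camera adjusted p = 0.399, and adjusted p = 0.622 with an estimated correlation), and 4 of 6 fell with the antibody (4 adjusted over the list alone, camera adjusted p = 0.0131, and adjusted p = 0.425 with an estimated correlation). Lymphocyte genes rose in 12 of 15 on adenine (12 adjusted over the list alone, camera adjusted p = 0.0122, and adjusted p = 0.304 with an estimated correlation), whereas 2 of 14 were lower with the antibody (1 adjusted over the list alone, camera adjusted p = 0.0523, and adjusted p = 0.447 with an estimated correlation). The lymphocyte list passed without antibody replicate 3 or IgG replicate 1 or 3 (adjusted p = 0.0118, 0.0255 and 0.0485), with RLE scaling (0.0469) and with the replicate block (0.0348). Interferon response genes were higher in 13 and lower in 4 of 26 on adenine (13 and 4 adjusted over the list alone, camera adjusted p = 0.122, and adjusted p = 0.667 with an estimated correlation). The antibody called neither the endothelial list (4 lower of 16, 4 adjusted over the list alone, camera adjusted p = 0.148, and adjusted p = 0.577 with an estimated correlation; adjusted p = 0.0474 without IgG replicate 1) nor the podocyte list (5 higher and 3 lower of 15, 6 and 3 adjusted over the list alone, camera adjusted p = 0.585, and adjusted p = 0.726 with an estimated correlation).

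The p53 target list was not called on adenine (14 higher and 5 lower of 21; camera adjusted p = 0.0753), with the knockout label (3 and 8; 0.400) or with the antibody (3 and 7; 0.274), with the same counts adjusted over the list alone and adjusted p = 0.355, 0.622 and 0.546 with an estimated correlation. Immediate early and heat shock genes were not called either (7 higher and 3 lower of 13, 4 and 5, and 1 and 3, the same adjusted over the list alone, camera adjusted p = 0.153, 0.315 and 0.274, and adjusted p = 0.482, 0.622 and 0.661 with an estimated correlation). Adipose tissue genes were lower in 6 and higher in 2 of 8 on adenine (6 and 2 adjusted over the list alone, camera adjusted p = 0.224, and adjusted p = 0.574 with an estimated correlation). With the knockout label 3 were higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.611, and adjusted p = 0.783 with an estimated correlation). Urothelium genes were lower in 7 of 7 on adenine (7 adjusted over the list alone, camera adjusted p = 0.0690, and adjusted p = 0.464 with an estimated correlation) and higher in 5 of 7 with the knockout label (5 adjusted over the list alone, camera adjusted p = 0.0786, and adjusted p = 0.529 with an estimated correlation). The former passed without wild-type replicate 5 (adjusted p = 0.0466), with upper-quartile scaling (0.0366) and with the replicate block (0.0376). The latter passed without knockout replicate 2 or wild-type replicate 5 (adjusted p = 0.0123 and 0.0242), with upper-quartile scaling (0.0376) and with the replicate block (0.0488).

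Enpp1 varied among the antibody libraries, with 9.51, 2.62, 3.26 and 17.4 CPM in replicates 1 to 4, beside 7.22 to 8.86 CPM with IgG. The transcript most abundant with IgG, where it took 74.7% to 82.6% of the Enpp1 reads, took 67.1%, 42.3%, 40.1% and 76.5% in those antibody libraries. In the knockout experiment that transcript took 86.3% to 89.3% in the libraries labelled knockout, 79.1% to 85.6% in wild type on adenine and 93.7% to 96.2% on chow, without overlap between these groups.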
